A study of Mus musculus with 20 samples.

How the data were processed

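Poly(A) RNA from mouse heart ventricles was sequenced in 20 libraries, 5 in each of 4 groups that combine 2 genotypes with 2 injections. Per the labels' protocols, tamoxifen was injected at 75 mg/kg on 4 days in male mice aged 6 to 8 weeks, and the hearts were taken 2 weeks after tamoxifen. Rapamycin at 1 mg/kg, or vehicle, was injected daily for 2 weeks. RNA was extracted with a kit for fibrous tissue and made into TruSeq libraries, which were sequenced in 4 pools, per the labels' protocols. Each pool held at least 1 library of every group, so pool and group are not confounded. The submitters' design text states 5 biological replicates per condition, and replicates count as separate animals here only as far as that text says so.

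Per the submitters' processing notes, the reads were set against the mouse build mm9, and Picard 1.64, SAMtools and RSEM were used. The versions of the last pair and the aligner are not given in the sources used here. The deposited values are a normalized expression signal per gene: RSEM estimates scaled by the authors so that the upper quartile of each library is the same. The file bears this out, since the 75th percentile of the values above 0 lay between 996.6 and 1000 in every library. The values are therefore not counts, and no test for counts was the main test. Gene symbols and Entrez identifiers were used as the file gives them. Of 21705 genes, 21562 had an identifier found in the RefSeq table of assembly GRCm38.p6, which was used for names and, through the transcript annotation, for lengths only. No coordinates were used.

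Low values were mostly whole multiples of 1 step per library, as scaled read counts would be. Between 77.6% and 87.3% of them came out whole within 0.05 reads. That share is too low to treat reads as recovered, since RSEM divides reads between genes. The step implies a total of 11.5 to 21.1 M reads per library (median 15.2 M). These implied totals served for depth and for 1 alternative.

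Values were analysed as log2(value + 1). A gene was tested when its value was at least 10 in at least 5 libraries, which left 13548 genes. The fitted change is on that log2(value + 1) scale and understates the change of genes near 0. All 20 libraries entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were knockout against control under vehicle, knockout against control under rapamycin, rapamycin against vehicle in control mice, rapamycin against vehicle in knockout mice, and the interaction, which is the difference between the first pair. The slope of the knockout effect under rapamycin on that under vehicle was fitted across the genes called under vehicle. These comparisons, the groups, the filter, the gene lists and most alternatives were fixed before the data were examined. The main effects of genotype and of drug, each averaged over the other factor, were added after seeing the data.

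Gene lists for metabolism, growth, stress, matrix and cell types were fixed before the data were examined, and 49 of them had at least 4 tested genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. Camera compares a list with the other genes. The directional fry test asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Within each list, p-values were also adjusted over the list alone. Single measures were compared with exact permutation tests, two-sided, over all regroupings of 5 against 5 libraries.

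The genes named in the text follow a rule fixed before the data were examined. It names Acsl1 in every comparison. It adds up to 8 genes in each direction with the largest changes among those that passed the adjusted threshold, had a mean of at least 100, and did not overlap between the groups. It adds the members with the smallest p-values of each called list, and 17 fixed heart and metabolism genes in the knockout comparison under vehicle. The rule asks for 4 members per called list. That number was used in the knockout comparison under vehicle, and 2 members were taken elsewhere for length. Some genes that the rule names are not reported here. Any other gene is said in the text to have been chosen after its values were seen.

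Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, no filter, a filter on a mean of at least 100, quantile normalization, median-ratio rescaling, a pool term, the replicate number as a block, a fit of only the groups compared, robust empirical Bayes with array weights, an estimated correlation for the list tests, and leaving out each library in turn. Alternatives added after seeing the data were a fit without control vehicle libraries 1 and 3, which stood apart on the first principal component, covariates for atrial transcripts and for a transcript length trend, limma's voom on the implied reads, and the slope without Esr1, A1cf and Acsl1. Alternatives that need read counts were not run. The length trend of a library is the median deviation of the longest 25% of genes minus that of the shortest 25%. It was computed from the 13207 tested genes with a known length, without the ribosomal protein and oxidative phosphorylation lists. All genes of those lists had a length.

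The tests were tried on simulated data with 200 changed genes before use. In the knockout comparison under vehicle, the test recovered 41.8%, 71.6% and 98.5% of simulated changes of 1.5, 2 and 4 times, and in the interaction it recovered 11.9%, 49.3% and 92.4%. For the genotype main effect the shares were 65.7%, 94.0% and 100%. The simulated noise was independent between genes and held no libraries that stood apart, so the shares in the real data may differ. The median standard error of a log2 change was 0.19 between groups, 0.27 for the interaction and 0.13 for the main effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads and sequence were not analysed here.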

Results

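Gene expression was measured by RNA sequencing in heart ventricles of male C57Bl/J6 mice. Mice that lost Acsl1 in the heart after tamoxifen (Acsl1H-/-, called knockout here) were set beside littermates with an intact floxed gene (Acsl1flox/flox, called control). A Cre recombinase removes a floxed gene, and control hearts kept Acsl1 although tamoxifen is part of the protocol for both genotypes. A Cre thus acted on the gene in knockout hearts alone. Any effect of that Cre was not told apart from the loss of Acsl1. Acsl1 encodes the long-chain acyl-CoA synthetase that activates fatty acids for oxidation in heart. Mice of both genotypes received rapamycin, an inhibitor of the growth kinase mTOR, or vehicle, which gave 4 groups of 5 libraries. The series asks how the heart responds early to the loss of this fuel and which part of the response depends on mTOR. Values are upper-quartile-normalized expression estimates, with an upper quartile of about 1000 in each library. The implied depth was 13.5 ± 2.31 M reads in control vehicle, 15.6 ± 3.19 M in knockout vehicle, 15.8 ± 3.38 M in control rapamycin and 16.4 ± 2.59 M in knockout rapamycin libraries (mean ± SD, n = 5 each). Between 14592 and 15605 genes lay above 0 in a library, and 13548 genes were tested. Control vehicle libraries 1 and 3 stood apart on the first principal component, which held 33.7% of the variance, with scores of 73.4 and 84.6. Their long transcripts were low against their short ones, with long-minus-short scores of -1.01 and -1.10, against -0.41 to 0.53 in the other 18 libraries.

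**Figure D1:**
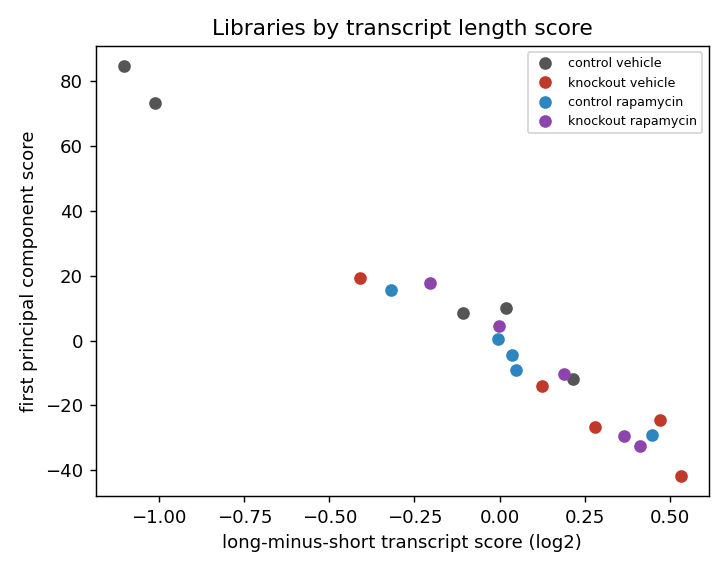
First principal component score (y axis) against the long-minus-short transcript score in log2 units (x axis), each point being 1 of the 20 libraries, coloured by group. Control vehicle libraries 1 and 3 lie apart, at long-minus-short scores of -1.01 and -1.10 and component scores of 73.4 and 84.6.

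Acsl1 (Entrez gene 14081) was low in every knockout library, so each library carried the genotype of its label. The 5 control vehicle libraries had values of 6373, 13112, 7659, 9844 and 13431, and the 5 knockout vehicle libraries 996, 1402, 1467, 1682 and 740.5. Under rapamycin the control libraries had 12198, 10518, 12121, 16661 and 11698, and the knockout libraries 1052, 1950, 948, 631 and 1539. Knockout hearts thus held 12.5% of the control mean under vehicle and 9.68% under rapamycin. The groups did not overlap in either arm, and the exact permutation test gave p = 0.00794 in each arm, the smallest value that 5 against 5 libraries allow.

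**Figure D2:**
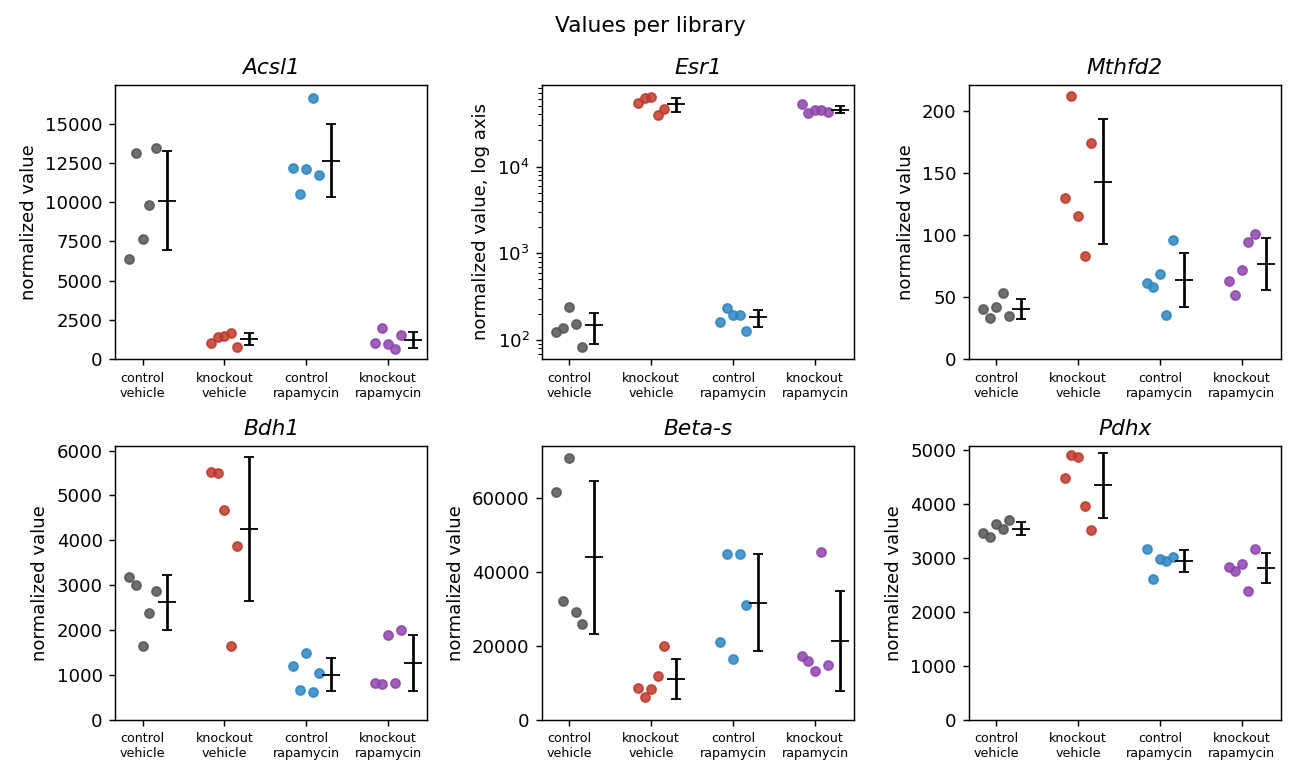
Normalized expression values (no unit; y axis) of Acsl1, Esr1, Mthfd2, Bdh1, Beta-s and Pdhx in the 4 groups (x axis), each point being 1 library and each tick with its bar the mean ± SD of 5 libraries; the axis of Esr1 is logarithmic. Acsl1 is low and Esr1 high in all 10 knockout libraries, and Bdh1 and Pdhx are lower in the rapamycin groups; these genes, apart from Acsl1, were chosen for the plot after their values were seen.

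In knockout hearts under vehicle, Acsl1 fell by 3.00 on the log2 scale (SE 0.28, adjusted p = 3.67e-06), and in the 4 pools the difference was -2.99, -3.22, -2.88 and -3.00. Among the genes that rose, Itgbl1, an extracellular protein with integrin-like repeats, was at 107 ± 39.5 in control and 360 ± 124 in knockout libraries (mean ± SD, n = 5 each; log2 change 1.73, SE 0.31, adjusted p = 0.0186). Myoc, the secreted protein myocilin, rose by 1.45 (SE 0.27, adjusted p = 0.0223), Col8a1, a short-chain collagen, by 1.43 (SE 0.29, adjusted p = 0.0413), and Svep1, a large matrix protein, by 1.22 (SE 0.25, adjusted p = 0.0456). Of other genes that rose, Gabra3 encodes a GABA receptor subunit (log2 change 1.07), Gcnt1 a glycan-branching enzyme (1.05) and Adcyap1r1 the receptor of the peptide PACAP (1.05). Esr1, the estrogen receptor gene, was at 148 ± 56.9 in control and 52658 ± 9701 in knockout libraries (log2 change 8.53, SE 0.21, adjusted p = 1.031e-16). Esr1 was called in all 10 fits with 1 library left out and all 14 alternatives, but Itgbl1, Myoc, Col8a1 and Svep1 were called in 6, 6, 4 and 5 of those fits and 9, 9, 7 and 4 alternatives, and Gabra3, Gcnt1 and Adcyap1r1 in 5, 4 and 6 fits and 6, 5 and 9 alternatives.

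Among the genes that fell, Chac1, which breaks down glutathione and is induced by amino acid stress, was at 433 ± 121 in control and 189 ± 65.5 in knockout libraries (log2 change -1.22, SE 0.24, adjusted p = 0.0305). Ano10, a membrane protein of the anoctamin family, was at 3186 ± 673 and 1646 ± 264 (log2 change -0.94, adjusted p = 0.0280). Egflam, the matrix protein pikachurin, was at 641 ± 39.1 and 391 ± 46.3 (log2 change -0.72, SE 0.10, adjusted p = 0.00295). The haemoglobin transcripts Beta-s (log2 change -2.0, SE 0.38, adjusted p = 0.0289) and Hba-a2 (-1.80, SE 0.37, adjusted p = 0.0404) fell too. Beta-s was at 43975 ± 20755 in control and 10969 ± 5375 in knockout libraries, and in the 4 pools its difference was -2.29, -2.39, -2.47 and -1.13. The control mean was raised by the libraries that stood apart, control vehicle 1 and 3, at 61652.5 and 70934, while the other 3 controls lay between 25898 and 32138.5. Without both the log2 change of Beta-s was -1.52, with an adjusted p of 0.420, the highest of its 14 alternatives (lowest 0.0283). Egflam was called in all 10 fits with 1 library left out and 13 of 14 alternatives, but Chac1, Ano10, Beta-s and Hba-a2 in only 5, 6, 5 and 4 of those fits and 10, 9, 9 and 6 alternatives. Haemoglobin genes share reads with near-identical copies, so the value of each single copy is uncertain.

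Genes outside the naming rule, chosen here after their values were seen, included Mthfd2, a mitochondrial enzyme of folate metabolism, at 40.8 ± 8.02 in control and 143 ± 50.7 in knockout libraries (log2 change 1.73, SE 0.27, adjusted p = 0.00625; 1.47, 2.64, 1.74 and 1.24 in the 4 pools). Pla2g4a, a phospholipase that frees arachidonic acid, was at 54.2 ± 5.10 and 128 ± 36.0 (log2 change 1.19, adjusted p = 0.00993), and Vcam1, an adhesion molecule, at 419.6 ± 87.1 and 770 ± 156 (log2 change 0.88, adjusted p = 0.0177). These 3 genes were called in 10, 10 and 8 of the 10 fits with 1 library left out, Mthfd2 and Pla2g4a in 11 and 9 of 13 alternatives and Vcam1 in 10 of 14. A1cf, an RNA-binding cofactor of messenger RNA editing, was listed at 0 in all 10 control libraries. It had values of 37.4, 22.5, 37.8, 18.7 and 22.5 in knockout vehicle and 27.5, 5.74, 17.2, 10.3 and 40.9 in knockout rapamycin libraries. The labels do not name the Cre line, and for neither Esr1 nor A1cf was transcription from the mouse gene told apart from reads due to a transgene.

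Among the fixed lists, 18 fibroblast markers lay higher in knockout vehicle hearts, with a median log2 change of 0.57 and a preset-correlation adjusted p of 0.000141 (adjusted p = 0.820 with an estimated correlation). Pdgfra, the receptor that marks cardiac fibroblasts, was at 769 ± 322 in control and 1581 ± 351 in knockout libraries, and Gsn, the actin-severing protein gelsolin, at 42960 ± 4929 and 64086 ± 12447; no member passed over all genes, and 10 were higher with p-values adjusted over the list alone. The directional fry test called this list as well (adjusted p = 0.0472). The 38 matrix and fibrosis genes had a median of 0.82 (adjusted p = 1.325e-06; adjusted p = 0.820 with an estimated correlation), with 1 member called over all genes, Col8a1, and 15 higher adjusted over the list alone. Cilp, a matrix protein of activated fibroblasts, was at 266 ± 126 and 1458 ± 1035, and Postn, periostin, at 641 ± 274 and 1795 ± 898, neither past the threshold over all genes (adjusted p = 0.0684 and 0.0717). The 8 erythroid transcripts had a median of -1.6 (adjusted p = 1.325e-06; adjusted p = 0.820 with an estimated correlation; fry adjusted p = 0.0472), with 2 members lower over all genes and 7 adjusted over the list alone. Alas2, the erythroid enzyme of haem synthesis, was at 1182 ± 532 and 371 ± 161. Both medians moved with control vehicle libraries 1 and 3, without which the matrix list lay at 0.52 and the erythroid list at -1.30, both still called with the preset correlation. The 14 atrial and conduction markers had a median of 1.69 (adjusted p = 0.00661; adjusted p = 0.820 with an estimated correlation), with none called over all genes and 4 higher adjusted over the list alone. Their expression varied widely within groups: Nppa, the atrial natriuretic peptide, was at 3003 ± 1890 in control and 17931 ± 13273 in knockout libraries, and Myl7, the atrial light chain, ran from 3.98 to 10265 over the 20 libraries.

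Other lists lay lower. The 74 cytosolic ribosomal protein genes had a median of -0.51 (adjusted p = 2.873e-17; adjusted p = 0.820 with an estimated correlation), with Rpl28 at 5473 ± 1294 in control and 3652 ± 1080 in knockout libraries. The 75 oxidative phosphorylation subunits had a median of -0.49 (adjusted p = 3.473e-16; adjusted p = 0.820 with an estimated correlation), with Cox5b, a subunit of the terminal oxidase, at 22462 ± 7175 and 13088 ± 3734. No member of either list passed over all genes or adjusted over the list alone. Both lists moved with the libraries that stood apart: without control vehicle libraries 1 and 3 their medians were -0.15 and -0.17, both still called with the preset correlation. Ribosomal protein genes also share reads with many near-identical pseudogenes. The lysosome and autophagy list (34 genes, median -0.17, adjusted p = 0.00168; adjusted p = 0.820 with an estimated correlation) held Bnip3, a mitophagy receptor, at 6361 ± 1074 and 4075 ± 821; 6 members were lower and 1 higher adjusted over the list alone, and the median was -0.06 without those 2 libraries. The antioxidant list had a median of -0.29 (27 genes, adjusted p = 0.0364; adjusted p = 0.820 with an estimated correlation), with Gstp1, a glutathione transferase, at 4764 ± 1231 and 3176 ± 627. The cell cycle list also had a median of -0.29 (34 genes, adjusted p = 0.0461; adjusted p = 0.820 with an estimated correlation), with Ccna2, cyclin A2, at 41.2 ± 4.34 and 23.4 ± 9.80. No member of the antioxidant and cell cycle lists passed over all genes or adjusted over the list alone. Without control vehicle libraries 1 and 3 the medians of these lists were -0.11 and -0.33, both still called with the preset correlation, as was the lysosome list.

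**Figure D3:**
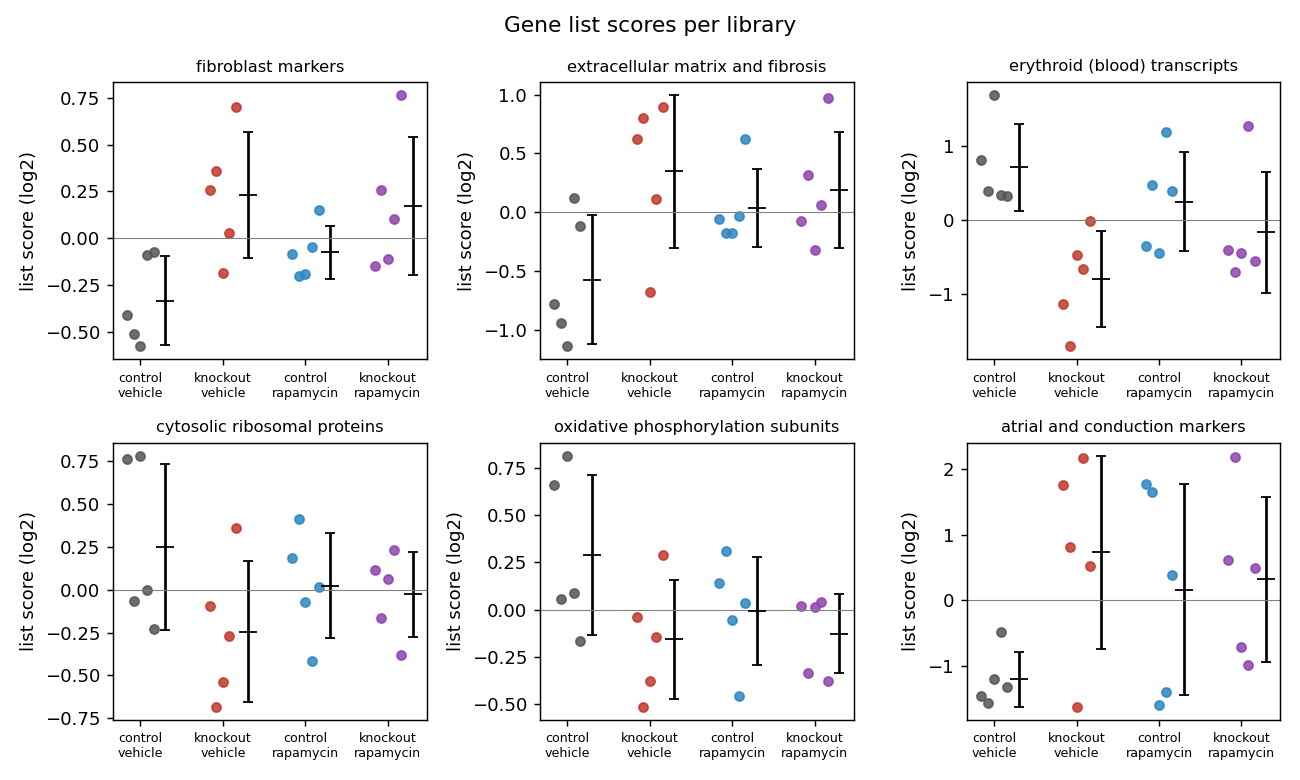
List scores (mean log2 value of the members of a list minus their mean over all libraries; y axis) of 6 gene lists in the 4 groups (x axis), each point being 1 library and each tick with its bar the mean ± SD of 5 libraries. The erythroid score was 0.71 ± 0.58 in control vehicle and -0.79 ± 0.65 in knockout vehicle libraries, and atrial scores spread widely within 3 of the groups.

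Of the fixed heart and fuel genes, none but Acsl1 passed the threshold in knockout hearts under vehicle. Myh7, the slow myosin heavy chain that rises in hypertrophy, was at 14569.5 ± 7292 in control and 28280.4 ± 7226 in knockout libraries (log2 change 1.10, adjusted p = 0.0799), and Nppb, the stress-induced natriuretic peptide, had a log2 change of 1.02 (adjusted p = 0.328). Acta1, skeletal actin, had 0.86 (adjusted p = 0.351) and Myh6, the fast myosin heavy chain, 0.73 (adjusted p = 0.142). Cpt1b, which carries fatty acids into mitochondria, was at 19941 ± 3264 and 19789 ± 687 (log2 change 0.00, adjusted p = 0.985). Ppara, the receptor that controls fatty acid genes, had a log2 change of 0.54 (adjusted p = 0.129), its coactivator Ppargc1a 0.55 (adjusted p = 0.193), Pdk4, which blocks pyruvate oxidation, 0.29 (adjusted p = 0.727), and the uncoupling protein gene Ucp3 0.24 (adjusted p = 0.752). The glucose transporters Slc2a1 and Slc2a4 had log2 changes of -0.49 (adjusted p = 0.0995) and -0.41 (adjusted p = 0.106), and hexokinase Hk2 0.45 (adjusted p = 0.166). Of the other long-chain acyl-CoA synthetases, Acsl3 had 0.67 (adjusted p = 0.148), Acsl4 0.16 (0.428), Acsl5 0.03 (0.898) and Acsl6 -0.03 (0.911).

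In all, limma called 33 of 13548 genes in knockout hearts under vehicle, 27 higher and 6 lower, and 4315 genes (31.8%) had an unadjusted p under 0.05. The split was 25 higher and 22 lower after quantile normalization. All 33 differed in the same direction in each of the 4 pools, where they had been picked for being called, but some differences were near 0 in pool 4, which held 1 library of each of these groups: 0.065 for Col8a1 (1.55, 2.25 and 2.03 in the others), 0.14 for Itgbl1 (1.91, 2.31 and 2.34) and 0.37 for Svep1 (1.31, 1.35 and 1.6). The count depended on single libraries: it was 8 without control vehicle 1, 9 without control vehicle 3, 11 without knockout vehicle 1, 8 without knockout vehicle 2, 343 without control vehicle 4, 2565 without knockout vehicle 5 and 3089 without control vehicle 5. It was 4 without control vehicle libraries 1 and 3 together, and 3 genes, Acsl1, Esr1 and A1cf, were called in every alternative fit that tested them; the cause was not tested.

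Under rapamycin, knockout and control hearts differed in 3 called genes, the question being how much of the knockout response remained while mTOR was inhibited. Acsl1 fell by 3.46 on the log2 scale (SE 0.28, adjusted p = 4.647e-07; -2.64, -3.65, -3.67 and -3.57 in the 4 pools). Esr1 was at 182 ± 39.7 in control and 45325 ± 3949 in knockout libraries (log2 change 7.97, adjusted p = 3.873e-16), and A1cf, listed at 0 in the controls, was the third. Of the 25 PPAR target genes, which serve fatty acid use, none was called over all genes and 1 was higher adjusted over the list alone. The list's median was 0.14 (adjusted p = 3.651e-07; adjusted p = 0.150 with an estimated correlation).

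The fibroblast list had a median of 0.27 under rapamycin (adjusted p = 1.369e-07; adjusted p = 0.264 with an estimated correlation), with 3 members higher adjusted over the list alone. They were Gsn (50032 in control and 71092 in knockout libraries), Dpep1, a membrane dipeptidase (1523 and 2206), and Dcn, decorin. The matrix list had a median of 0.11 (adjusted p = 0.00309; adjusted p = 0.779 with an estimated correlation), where Cilp had a log2 change of 1.09. The cell cycle list had a median of -0.39 (adjusted p = 9.459e-07; adjusted p = 0.264 with an estimated correlation), with Ccna2 at a log2 change of -1.07. The skeletal muscle list had a median of -0.23 (adjusted p = 0.0138; adjusted p = 0.264 with an estimated correlation), with 1 member lower adjusted over the list alone: Casq1, the calsequestrin of fast skeletal muscle, at 496 ± 229 and 146 ± 79.6. The nerve list had a median of 0.21 (adjusted p = 0.0475; adjusted p = 0.719 with an estimated correlation), with Scn7a, a sodium channel subunit, at 588 and 870.2.

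Of the fuel lists, fatty acid oxidation had a median of 0.09 (adjusted p = 0.00198; adjusted p = 0.290 with an estimated correlation), fatty acid uptake 0.07 (adjusted p = 0.0337; adjusted p = 0.264 with an estimated correlation) and fatty acid synthesis 0.15 (adjusted p = 0.0155; adjusted p = 0.365 with an estimated correlation). Decr1, which helps to oxidize unsaturated fatty acids, had a log2 change of 0.21. Oxidative phosphorylation had a median of -0.12 (adjusted p = 0.00243; adjusted p = 0.852 with an estimated correlation) and the erythroid list -0.46 (adjusted p = 0.0292; adjusted p = 0.778 with an estimated correlation). The unfolded protein response list lay at -0.14 (adjusted p = 0.0475; adjusted p = 0.778 with an estimated correlation), the glucocorticoid list at 0.21 (adjusted p = 0.0292; adjusted p = 0.778 with an estimated correlation) and the cardiac transcription factors at 0.05 (adjusted p = 0.0138; adjusted p = 0.699 with an estimated correlation). Limma called 2 genes higher and 1 lower, which all remained called without any 1 library, with 403 genes at an unadjusted p under 0.05 and 3 genes by voom. Of the 49 lists 14 were called with the preset correlation, 8 without control rapamycin 5, and 0 with an estimated one.

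In control hearts, the effect of rapamycin itself was asked, and no gene was called. The lowest p-values among the list members belonged to enzymes that break down branched-chain amino acids. Bcat2, the mitochondrial transaminase of those amino acids, was at 3506 ± 511 under vehicle and 2239 ± 205 under rapamycin (log2 change -0.64, SE 0.12, adjusted p = 0.225). Bckdhb, a subunit of the dehydrogenase that follows it, was at 2600 ± 493 and 1819 ± 160 (log2 change -0.50, adjusted p = 0.225). The list of ketone and branched-chain amino acid breakdown had a median of -0.06 (adjusted p = 0.00662; adjusted p = 0.800 with an estimated correlation), with 1 member higher and 3 lower, Bcat2, Bckdhb and Bdh1, adjusted over the list alone. Acsl1 had a log2 change of 0.37 (adjusted p = 0.460).

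Higher lists in control hearts under rapamycin were the matrix list (median 0.54) and the atrial list (median 1.14), and lower ones were ribosomal proteins (-0.24), oxidative phosphorylation (-0.32), lysosome (-0.11), antioxidant (-0.19), glycolysis (-0.13), phospholipid (-0.15) and erythroid genes (-0.44). Each was called only with the preset correlation (adjusted p = 0.800 with an estimated correlation for all of them). Members named by the rule included Thbs1, a matrix glycoprotein (log2 change 1.73, adjusted p = 0.328), Tgfb2, a growth factor (0.99), Gys1, glycogen synthase (-0.30), and Tbx3, a conduction-system factor (0.46), and none passed. Without control vehicle libraries 1 and 3 the median of the ribosomal list was 0.12 and that of oxidative phosphorylation 0.00, the matrix list lay at 0.24 and the erythroid list at -0.016. The lysosome, phospholipid and antioxidant lists then lay at 0.018, 0.0091 and -0.011, none of them called. Still called in the same direction were 4 of the 10 lists, among them glycolysis at -0.083 and the atrial list at 1.12. Limma called 0 of 13548 genes, with 2024 at an unadjusted p under 0.05 and a smallest adjusted p of 0.225, and voom and the other alternatives called 0 as well. With the preset correlation 10 lists were called, 17 without control vehicle 1, and 0 with an estimated one.

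In knockout hearts, 1 gene fell under rapamycin. Pdhx, the component of the pyruvate dehydrogenase complex that binds its E3 enzyme, was at 4347 ± 602 under vehicle and 2804 ± 279 under rapamycin (log2 change -0.63, SE 0.10, adjusted p = 0.0467; -0.70, -0.79, -0.52 and -0.53 in the 4 pools). In the ketone and branched-chain amino acid list, Bdh1, which converts ketone bodies, was at 4245 ± 1604 and 1264 ± 621 (log2 change -1.76, SE 0.34, adjusted p = 0.152), and Bcat2 was at 3143 and 2237 (-0.48, adjusted p = 0.189). That list had a median of -0.29 (adjusted p = 2.809e-05; adjusted p = 0.502 with an estimated correlation), with 7 members lower (Bcat2, Bckdhb, Bdh1, Hibadh, Mccc2, Oxct1 and Pcca) and 1 higher adjusted over the list alone.

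Of the PPAR target genes 3 were higher in knockout hearts under rapamycin adjusted over the list alone, among them Acot1, a thioesterase, and Cd36, a fatty acid transporter, and the list's median was 0.10 (adjusted p = 0.00602; adjusted p = 0.502 with an estimated correlation). The ribosomal list lay at 0.22 and the lysosome list at 0.07 (adjusted p = 0.660 for both with an estimated correlation), antioxidant genes at 0.06, erythroid transcripts at 0.77, nerve genes at 0.35 and immediate early genes at 0.22 (adjusted p = 0.595 for these 4 with an estimated correlation). Among the immediate early genes Nr4a3, a nuclear receptor, was higher adjusted over the list alone (log2 change 2.37, adjusted p = 0.159 over all genes). Macrophage markers lay at -0.17 and cardiac transcription factors at 0.13 (adjusted p = 0.612 for both with an estimated correlation), interferon-induced genes at -0.23 (adjusted p = 0.744 with an estimated correlation) and antigen presentation genes at 0.42 (adjusted p = 0.660 with an estimated correlation). Acsl1 had a log2 change of -0.09 (adjusted p = 1.00).

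The single call in this comparison was fragile. Pdhx was called in 6 of 14 alternatives, with adjusted p-values from 0.00114 to 0.342, and voom called 0 genes, as did the fits with a pool term (Pdhx adjusted p = 0.210) and with a replicate block (0.197). The limma count was 0 without knockout vehicle 1, 2 or 3 or knockout rapamycin 1, 2, 3 or 4, and 2 without knockout vehicle 4. At an unadjusted p under 0.05 there were 774 genes, and 12 lists were called with the preset correlation and 0 with an estimated one.

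Whether the knockout effect differed between the drug arms was tested as an interaction. Acsl1 itself had an interaction of -0.45 (SE 0.39, adjusted p = 0.594). The 33 genes called under vehicle all differed in the same direction under rapamycin, with a slope of 0.77 of the rapamycin arm on the vehicle arm. Without Esr1, A1cf and Acsl1, a choice made after seeing the data, the slope was 0.37. All 30 other genes had the smaller change under rapamycin, with medians of 1.04 under vehicle and 0.40 under rapamycin in the vehicle direction. These genes were selected for their change in the vehicle arm, which by itself makes their change in the other arm smaller. The slope was 0.35 without control vehicle 4, 0.14 without control vehicle 5 and 0.13 without knockout vehicle 5. Each of these was taken over the genes called in its own fit, which were far more than 33, so they do not describe the same genes.

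Named members had interactions of 1.37 for Beta-s, 0.74 for Cox5b, 0.66 for Rpl28, 0.59 for Slc2a1, 0.54 for Bnip3, -1.08 for Col8a1 and -3.29 for Spp1, the matrix protein osteopontin, all with an adjusted p of 0.523. Limma called 0 of 13548 genes, with 1124 at an unadjusted p under 0.05, and voom called 0. Of the 33 genes called under vehicle, 20 had an unadjusted interaction p under 0.05. They were selected for their change under vehicle, which is part of the interaction, so selection by itself raises that count. With 0 genes called, a difference between the arms was not shown for any single gene. The test recovered 11.9% of simulated interactions of 1.5-fold and 92.4% of those of 4-fold, with noise simulated independently for each gene. With the preset correlation 11 lists were called, 7 without knockout vehicle 5, and with an estimated one 0 were (smallest adjusted p 0.660).

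Averaged over both drug arms, a comparison added after seeing the data, 4 fibroblast and matrix genes were among those called in knockout hearts. Gsn rose by 0.53 (SE 0.10, adjusted p = 0.0191; 0.55, 0.27, 0.81 and 0.51 in the 4 pools), Pdgfra by 0.83 (SE 0.17, adjusted p = 0.0391), Cilp by 1.6 (SE 0.36, adjusted p = 0.0434) and Dcn by 0.44 (adjusted p = 0.0422). Gsn was called in 11 of 13 alternatives and without any 1 of the 20 libraries, but Pdgfra, Cilp and Dcn in 9, 6 and 7 alternatives, and in 9, 6 and 6 of the 20 fits with 1 library left out. Parm1, a mucin-like membrane protein, was at 1412 ± 320 and 1406 ± 120 in control vehicle and control rapamycin libraries, and at 1901 ± 89.3 and 2040.3 ± 106 in the knockout groups (log2 change 0.50, SE 0.09, adjusted p = 0.0191; 0.45, 0.37, 0.81 and 0.41 in the 4 pools). The secreted proteins Sfrp1 (log2 change 0.82, adjusted p = 0.0187), Sfrp2 (1.12, adjusted p = 0.0391) and Frzb (1.10, adjusted p = 0.0484) were called too, in 12, 8 and 9 of 13 alternatives and in 20, 7 and 6 of the 20 fits with 1 library left out. Also higher were Gpm6b, a proteolipid membrane protein (0.74, adjusted p = 0.00160), Scn7a (0.68, adjusted p = 0.0103) and Mthfd2 (1.01, adjusted p = 0.0196). Acsl1 fell by 3.23 (adjusted p = 2.85e-09), Egflam by 0.52 (adjusted p = 0.00160) and Beta-s by 1.31 (SE 0.27, adjusted p = 0.0391; called in 7 of 13 alternatives and 8 of 20 fits with 1 library left out). Some of these genes were named here after their values were seen, among them Mthfd2, Sfrp1, Sfrp2 and Frzb.

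The fibroblast list had a genotype median of 0.43, with 3 members called over all genes and 8 adjusted over the list alone (adjusted p = 0.688 with an estimated correlation; fry adjusted p = 0.0339). The matrix list had a median of 0.48, with 1 member called and 9 adjusted over the list alone (adjusted p = 0.812 with an estimated correlation), and the erythroid list -1.03, with 2 and 7 (adjusted p = 0.688 with an estimated correlation). Cell cycle genes lay at -0.33, with Ccna2 and Prc1, a protein of the dividing spindle, lower adjusted over the list alone, oxidative phosphorylation at -0.31 and atrial markers at 0.84 (adjusted p = 0.812 for these 3 with an estimated correlation). The ribosomal list lay at -0.28 (adjusted p = 0.825 with an estimated correlation) and the lysosome list at -0.06 (adjusted p = 0.827 with an estimated correlation). Without control vehicle libraries 1 and 3 the matrix median was 0.30 and the fibroblast median 0.36. Oxidative phosphorylation then lay at -0.14, the ribosomal list at -0.10, the erythroid list at -0.88, atrial markers at 0.75 and cell cycle genes at -0.39. These 7 lists were still called with the preset correlation, but the lysosome list, at -0.017, was not. Limma called 60 genes, 45 higher and 15 lower, and voom called 59. Genes called in every alternative that tested them numbered 11, among them Parm1, Egflam, Gpm6b and Scn7a in 13 and A1cf in 12. The count was 21 without control rapamycin 2, 21 without knockout rapamycin 5, 22 and 23 without knockout vehicle 2 and 1, 26 and 27 without control vehicle 1 and 3, 27 and 39 without control rapamycin 3 and 1, 28 and 36 without knockout rapamycin 2 and 3, and 150 without control vehicle 5; it was 11 without control vehicle 1 and 3 together.

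Averaged over both genotypes, a comparison also added after seeing the data, transcripts of some enzymes of ketone, amino acid and pyruvate metabolism fell under rapamycin. Bdh1 (Entrez gene 71911) was at 2616 ± 617 in control vehicle and 4245 ± 1604 in knockout vehicle libraries, and at 1009 ± 363 and 1264 ± 621 in the rapamycin groups (log2 change -1.59, SE 0.24, adjusted p = 0.0129; -1.82, -2.54, -0.89 and -0.86 in the 4 pools). Bcat2 fell by 0.56 (SE 0.08, adjusted p = 0.0129; -0.59, -0.82, -0.31 and -0.55 in the 4 pools) and Pdhx by 0.45 (SE 0.07, adjusted p = 0.0129; -0.36, -0.55, -0.43 and -0.44 in the 4 pools). Bckdhb fell by 0.39 (adjusted p = 0.0499), Ccbl2, an aminotransferase, by 0.55 (adjusted p = 0.0245), Abat, which breaks down GABA, by 1.06 (adjusted p = 0.0480), Slc25a13, the mitochondrial aspartate carrier, by 0.41 (adjusted p = 0.0402), and Ckb, brain creatine kinase, by 0.75 (adjusted p = 0.0418). The mitochondrial factors Yars2, a transfer RNA synthetase, and Atpaf1, which assembles ATP synthase, fell by 0.43 and 0.32 (adjusted p = 0.0440 for both). Retnla, a secreted protein of alternatively activated macrophages, rose by 1.26 (adjusted p = 0.0418). Abat, Slc25a13, Ckb and Retnla were not given by the naming rule for this comparison and were chosen here after their values were seen.

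The ketone and branched-chain amino acid list had a drug median of -0.19, with 3 members lower and 1 higher over all genes and 6 and 1 adjusted over the list alone (adjusted p = 1.609e-06; adjusted p = 0.673 with an estimated correlation). The fry test for change in either direction called it (adjusted p = 2.594e-05). Glycolysis lay at -0.09, the citric acid cycle at -0.08, macrophage markers at -0.15, nerve genes at 0.34, immediate early genes at 0.25 and cardiac transcription factors at 0.14 (adjusted p = 0.673 for these 6 with an estimated correlation), and oxidative phosphorylation at -0.14 (adjusted p = 0.790 with an estimated correlation). Without control vehicle libraries 1 and 3, oxidative phosphorylation lay at 0.026, cardiac transcription factors at 0.041 and nerve genes at 0.27. These lists were then no longer called with the preset correlation. The ketone and branched-chain amino acid list lay at -0.19, glycolysis at -0.053, the citric acid cycle at -0.068, macrophage markers at -0.11 and immediate early genes at 0.21, all still called. Acsl1 had a log2 change of 0.14 (adjusted p = 0.809) with all libraries. Limma called 17 genes, 3 higher and 14 lower, with 1251 at an unadjusted p under 0.05, and voom called 25.

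The drug count was 0 with a pool term, where Bdh1, Bcat2 and Pdhx had adjusted p-values of 0.0592, 0.0528 and 0.0592, the highest of their 13 alternatives (lowest 0.00275, 0.00123 and 0.000415). These 3 genes were called without any 1 of the 20 libraries, but the 8 other genes named above in 2 (Bckdhb and Atpaf1) to 16 (Ccbl2) of those 20 fits, and the count was 3 without control vehicle 1 or 2, knockout vehicle 2 or knockout rapamycin 2, and 4 without control vehicle 3, knockout vehicle 1 or knockout rapamycin 1, 3 or 4. It was 5 without control rapamycin 2 or 3, 6 without control rapamycin 4, 7 and 8 without knockout vehicle 5 and 4, and 10 without control rapamycin 5.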

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

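The tests in this part without control vehicle libraries 1 and 3, with the transcript length covariate, under rapamycin and on the atrial transcripts were chosen after the data were seen.

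Knockout rapamycin library 4 lay far from the other 4 libraries of its group for 4 genes. It had Beta-s at 45407 against 13180 to 17348 and Hba-a2 at 49829.9 against 13969 to 19315, both haemoglobin transcripts. It had Ppara at 2399 against 2873 to 3010.0, and Acsl3 at 71.9 against 147 to 176. These were 4 of 132 groups of values tested, and chance alone marks about 1 in 20 groups; no explanation was tested.

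By the preset-correlation list test alone, 11 lists had a knockout effect that differed between the drug arms, given here as the median log2 effect under rapamycin minus that under vehicle. Lists with a higher effect under rapamycin were erythroid transcripts (1.21), glucocorticoid and fasting response (0.557), ribosomal proteins (0.463), oxidative phosphorylation (0.348), antioxidant genes (0.284), lysosome and autophagy (0.189), glycolysis (0.151), PPAR targets (0.134) and fatty acid uptake (0.121, although the mean of this last list was below 0). Lists with a lower effect were atrial markers (-1.67) and matrix genes (-0.757). With an estimated correlation none was called, with adjusted p-values from 0.660 to 0.899. No single gene of any of these lists had an interaction past the threshold. Without both control vehicle libraries that stood apart, every median was smaller in size. Oxidative phosphorylation then lay at 0.022 and glycolysis at 0.050, neither called with the preset correlation. The other lists were still called in the same direction. Among them were ribosomal proteins (0.107), antioxidant genes (0.126), matrix genes (-0.403), erythroid transcripts (0.838) and atrial markers (-1.51).

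The lower ribosomal protein and oxidative phosphorylation lists in knockout hearts under vehicle were weighed. Their mean score differed by -0.494 and -0.446, and without control vehicle libraries 1 and 3 by -0.145 (SE 0.224) and -0.148 (SE 0.188). With the long-minus-short score as a covariate the differences were 0.0377 (SE 0.0715) and 0.00172 (SE 0.0660), so a trend with transcript length between libraries, strongest in those 2 control libraries, may account for both lists. If the loss of Acsl1 acted alike with or without the drug, the lists would be lower under rapamycin too, where the differences were -0.0519 (SE 0.236) and -0.121 (SE 0.20), with errors too large to decide. An effect of Acsl1 loss on these lists and the length trend cannot be told apart, because the trend itself differs between the libraries of the groups compared.

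Atrial transcripts were high in some libraries of every group but control vehicle. The highest Myl7 value was 9549 in knockout vehicle, 9675 in control rapamycin and 10265 in knockout rapamycin, but 356 in control vehicle. If atrial tissue had entered some ventricle samples, the atrial light chain transcripts Myl7 and Myl4 would keep 1 ratio: over the 11 libraries with Myl7 at 100 or more, the SD of log2(Myl7/Myl4) was 0.147, while Myl7 spanned 4.85 on the log2 scale over the same libraries. In the other libraries the ratio was not kept (Myl7 at 3.98 and Myl4 at 49.7 in knockout vehicle 3). Myl4 did not fall below 49.7 in any library, so those with low Myl7 do not test the ratio. The atrial marker Bmp10 did not keep a ratio to Myl7 even where Myl7 was high. It was listed at 0 in control rapamycin 1 and 2 (Myl7 at 9675 and 7668). In knockout rapamycin 2 and knockout vehicle 4 it was at 1166 and 1733 (Myl7 at 10265 and 9549). In these 4 libraries, in that order, Mybphl was at 783, 617, 1102 and 1286. Sln was at 1628, 1534, 2542 and 2823, so both were high along with Myl7. The kept ratio of Myl7 to Myl4 leaves atrial tissue as a candidate source. Bmp10 argues against a source of 1 fixed makeup, but not against atrial tissue whose makeup differed between libraries. An atrial program switched on in ventricle could keep the first ratio as well, so the source stays open. Libraries with Myl7 at 100 or more numbered 7 of 10 in knockout and 4 of 10 in control hearts (odds ratio 3.27, 95% interval 0.406 to 33.3). Fisher's exact test, two-sided, gave p = 0.370, with too few libraries to decide whether the loss of Acsl1 had a part.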

How the results depend on the processing

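The fits without control vehicle libraries 1 and 3, the atrial and length covariates, voom, the slope without 3 genes and both main effects were chosen after seeing the data; the other alternatives were fixed before.

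Direction was stable for most named results, and counts were not. Of the other results in alternatives, 6474 values of single genes kept their direction and their side of the threshold, 1267 lost the call, 120 gained one and 44 reversed. For lists 1703, 327, 0 and 10 did so, by the direction of the list test and not the sign of the median. Some medians changed sign among those counted as a lost call. Without control vehicle libraries 1 and 3 the lysosome list for rapamycin in control went from -0.11 to 0.018. Acsl1, Esr1 and A1cf were called in every alternative that tested them in both knockout comparisons, and 8 of the 33 genes called under vehicle without any 1 library. Of 60 genes called for the genotype main effect 11 were called in every alternative that tested them and 19 without any 1 library, and of 17 for the drug main effect 0 and 3. No list call held with an estimated correlation.

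Called genes ranged from 3 to 56 over 14 alternatives in knockout against control under vehicle (33), from 2 to 14 under rapamycin (3), from 0 to 227 for rapamycin in knockout hearts (1), from 11 to 131 over 13 alternatives for the genotype main effect (60) and from 0 to 309 for the drug main effect (17). They were 0 in all alternatives for rapamycin in control hearts and for the interaction, where limma had 2024 and 1124 genes at an unadjusted p under 0.05. Where a value below moved, the cause was not tested.

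With a pool term the counts were 56 (knockout, vehicle), 0 (rapamycin in knockout) and 0 (drug main effect), and Cpt1b was at -0.016. With only the groups compared in the fit, which leaves fewer samples to estimate the spread, they were 3 and 0 for knockout under vehicle and rapamycin in knockout. With robust empirical Bayes and array weights they were 12 (knockout, vehicle), 14 (knockout, rapamycin), 58 (rapamycin in knockout), 131 (genotype) and 35 (drug), with 16 lists for rapamycin in control, Ucp3 at -0.11 and Acsl6 at 0.19. With no filter, 8 lists were called for knockout under rapamycin and 37 genes for the genotype main effect, and with the filter on the mean the cell cycle list was at 0.055 in knockout under vehicle, over fewer genes.

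Quantile normalization gave 0 genes for rapamycin in knockout, 13 lists for the genotype main effect and Acsl5 at -0.050. It moved the median of all genes by -0.11 in knockout under vehicle (from 0.07 to -0.04) and by 0.12 in the interaction (from -0.09 to 0.03); the split of calls went from 27 higher and 6 lower to 25 and 22 under vehicle, and from 45 and 15 to 49 and 32 for the genotype main effect. Median-ratio rescaling gave 0 genes for rapamycin in knockout, with Cpt1b at -0.049 and Acsl5 at -0.024. Voom on the implied reads gave 0 genes for rapamycin in knockout, with Acsl6 at 0.077. With an estimated correlation 0 lists were called in each of the 7 comparisons.

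Without control vehicle libraries 1 and 3, counts were 4 (knockout, vehicle), 0 (rapamycin in knockout), 11 (genotype) and 4 (drug), with 16 lists in knockout under vehicle and the ribosomal list at 0.12 for rapamycin in control. Pdk4 was at -0.28, Ucp3 at -0.34, Acsl4 at -0.046 and Acsl6 at 0.10 in knockout under vehicle, and Acsl1 at -0.016 for the drug main effect. With the atrial covariate, counts were 7 (knockout, vehicle), 0 (rapamycin in knockout) and 29 (genotype), with 6 lists for rapamycin in control and 6 for the interaction, Cpt1b at -0.0057 and Acsl5 at -0.10. With the length covariate, counts were 6 (knockout, vehicle), 227 (rapamycin in knockout) and 309 (drug), with 14 lists for the genotype main effect. The ribosomal list was then at 0.038 in knockout under vehicle, 0.17 for rapamycin in control and 0.039 for genotype, oxidative phosphorylation at 0.034 for rapamycin in control and -0.032 for the interaction, and the lysosome list at 0.053 and 0.023 for rapamycin in control and genotype. Single genes that reversed were Myh6 (-0.065), Ppargc1a (-0.039), Pdk4 (-0.045), Ucp3 (-0.14), Hk2 (-0.040), Acsl4 (-0.078) and Acsl6 (0.056) in knockout under vehicle, Rpl35 for rapamycin in control (0.015), and Acsl1 for rapamycin in control (-0.066), the interaction (0.025) and drug (-0.053).

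The replicate block gave 0 genes for rapamycin in knockout and 5 for the drug main effect, and 49 for knockout under vehicle. Replicate numbers did not pair the samples: over 30 same-numbered pairs the correlation of deviations ran from -0.51 to 0.43, 10 pairs were over 0.1, and 4 of 20 libraries correlated best with their own number. Over 36 pairs of 1 pool it ran from -0.37 to 0.43.

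The slope of 0.77 ranged from 0.37, without Esr1, A1cf and Acsl1, to 1.06, with the arms exchanged. The exchanged slope rests on only the 3 genes called under rapamycin, Acsl1, Esr1 and A1cf. It therefore cannot show how far selection in the vehicle arm lowers the slope. With 1 library left out, the slope of the rapamycin arm on the vehicle arm ran from 0.13 to 0.90. In these fits and the alternative fits it was taken over the genes that each fit called, so the gene sets differ. Counts of genes then ran from 8 to 3089 in knockout under vehicle, 0 to 2 for rapamycin in knockout, 21 to 150 for genotype and 3 to 17 for drug, and counts of lists from 8 to 16 for knockout under rapamycin, 7 to 17 for rapamycin in control and 7 to 15 for the interaction. The interferon list in rapamycin against vehicle in knockout ran from -0.43 to 0.11. In knockout under vehicle Cpt1b ran from -0.058 to 0.087, Pdk4 from -0.13 to 0.75, Ucp3 from -0.070 to 0.60, Acsl5 from -0.070 to 0.12 and Acsl6 from -0.12 to 0.073, and Acsl1 for rapamycin in knockout from -0.28 to 0.13.

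Depth and numbers limit what could be seen. With 5 libraries a group, the test called 41.8% of simulated changes of 1.5-fold in knockout under vehicle and 98.5% of those of 4-fold, so small changes can be missed. The simulation had independent noise for each gene and no libraries that stood apart, so the real shares may differ. Genes near the filter of 10 rest on few reads. Alternatives that need read counts were not run.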

Other observations

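The tests on Esr1 in this part were chosen after its values were seen, and the gene lists described first were singled out after their values were seen.

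Genes of serine, glycine and one-carbon metabolism, which supply carbon units for nucleotide synthesis, lay higher in knockout hearts under vehicle, with a median log2 change of 0.27 over 16 measured genes. Mthfd2 rose over all genes, and Aldh1l2, the mitochondrial folate enzyme that releases those units, and Slc1a5, a glutamine transporter, were also higher adjusted over the list alone. Aldh1l2 was at 57.6 ± 35.2 in control and 178 ± 87.3 in knockout libraries (mean ± SD, n = 5 each), and Slc1a5 at 336 ± 43.6 and 535 ± 118. The directional fry test called the list (adjusted p = 0.0362) and camera did not (adjusted p = 0.198 with the preset correlation and adjusted p = 0.820 with an estimated correlation). Under rapamycin the median was 0.07, and Mthfd2 was at 63.9 ± 21.8 in control and 76.6 ± 20.9 in knockout libraries. Its interaction was -1.45 (SE 0.38), with an adjusted p of 0.523, so a difference between the arms was not shown.

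Lists on amino acid stress, growth and hypertrophy were not called in knockout hearts under vehicle. The ATF4 and amino acid response list had a median of 0.16 (26 genes), with Ddit3, a stress transcription factor, and Gdf15, a stress hormone, higher and Chac1 and Eif4ebp1, a translation repressor, lower adjusted over the list alone. Ddit3 was at 185 ± 23.0 in control and 247 ± 24.1 in knockout libraries, and Atf4 at 985 ± 359 and 1369 ± 455. The fetal and hypertrophy list had a median of 0.64 (25 genes, adjusted p = 0.125 with the preset correlation), with Ankrd1, Cilp, Gdf15, Myh7, Nppa and Xirp2 higher and Ces1d and Csrp3 lower adjusted over the list alone. Its median was -0.04 under rapamycin. The atrial markers moved with it, with a median of 1.69 under vehicle and 0.07 under rapamycin, and Nppa, which is in both lists, was at 38847 in knockout vehicle library 4, where Myl7 was at 9549, and at 4087 in knockout vehicle library 3, where Myl7 was at 3.98. Components of the mTOR pathway had a median of -0.07 (34 genes), and mitochondrial fatty acid oxidation 0.12 (27 genes), with no member of the latter called over all genes or adjusted over the list alone.

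Esr1 was high in every knockout library. If tamoxifen itself had raised it, the control libraries would be high too, where tamoxifen is part of the protocol for both genotypes; their highest value was 239 and the lowest knockout value 39614. Reads from a tamoxifen-inducible Cre transgene that carries part of the estrogen receptor may account for it: the lowest knockout library was at 166 times the highest control library in the arm with the smaller ratio. A strong induction of the mouse gene by the loss of Acsl1 predicts the same ratio, and the labels used here do not name the Cre line. A1cf, listed at 0 in every control library and above 0 in every knockout library, is open to the same doubt, for which no test was run. Reads over single exons were not analysed here. Control hearts kept Acsl1 (6373 to 16661, against 631 to 1950 in knockout hearts). A Cre thus acted on the floxed gene in knockout hearts alone. An effect of that Cre and the loss of Acsl1 cannot be told apart in any knockout comparison.

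The knockout effect under vehicle and the rapamycin effect in control hearts use the same control vehicle libraries. Across 13548 genes, which are not independent replicates, their log2 changes had r = 0.78 and a covariance of 0.143, against 0.0378 in 100 simulations of unchanged groups with shared controls. With the control libraries split between the comparisons in 20 ways, the covariance averaged 0.0865 and ran from 0.00803 to 0.128. The shared control libraries include those that stood apart on the first principal component, and a split can put such a library on each side. How far those libraries raise the covariance was not tested. The excess over the simulated value therefore does not show an effect common to knockout and rapamycin. The knockout effect under vehicle and the rapamycin effect in knockout hearts share the knockout vehicle libraries, with r = -0.40 and a covariance of -0.0521, against -0.0379 simulated and -0.0117 on average over splits, which ran from -0.0585 to 0.0477, on both sides of 0. Between comparisons with no library in common, the knockout effects in the drug arms had r = 0.27 and the rapamycin effects in the genotypes r = -0.05 across genes.

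The samples of each comparison were also regrouped at random, with 100 groupings counted, the real one included. For the number of changed genes, few groupings gave as many as the real one in the comparisons given first, with no correction for the number of counts tested. Under rapamycin 1 grouping did (3 genes, highest other 1). These genes were Acsl1, the deleted gene, and Esr1 and A1cf, so that count tests the genotype labels and not a wider response. The same 3 genes are among those of the genotype main effect, where 2 groupings gave as many (60 genes, highest other 3953). For rapamycin in knockout hearts 3 groupings did (1 gene, highest other 1). That gene, Pdhx, was called in 6 of 14 alternatives and 3 of 10 fits with 1 library left out. The fits with a pool term and with a replicate block called 0 genes there. For the drug main effect 1 grouping did (17 genes, highest other 0), and the fit with a pool term called 0 genes. Both main effects were added after seeing the data. The groupings did not take account of pool. Chance cannot be excluded for knockout against control under vehicle (33; highest other 5344; 7 groupings). For rapamycin in control hearts (highest other 2881) and the interaction (highest other 1) the real count was 0, which all 100 groupings reach by construction, so the regrouping tests nothing there. Groupings that call many times more genes than the real one, seen for knockout against control under vehicle, rapamycin in control hearts and the genotype main effect, point to a structure of the samples other than their groups; they were not seen in the other 4 comparisons. For the number of called lists chance cannot be excluded in any comparison. The order here is knockout under rapamycin, rapamycin in knockout hearts, genotype, drug, knockout under vehicle, rapamycin in control hearts and interaction. The real counts were 14, 12, 8, 8, 9, 10 and 11, and the highest others 22, 24, 23, 18, 22, 19 and 22. As many were given by 21, 56, 71, 79, 69, 40 and 54 groupings. Calls of whole lists with the preset correlation are therefore weak evidence.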
